A study of Mus musculus with 8 samples.

How the data were processed

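Single-cell RNA-seq was made from epithelial cells of the mouse colon and cecum, taken from control (Ctrl), antibiotic-treated (Abx) and germ-free (GF) mice, per the labels. The labels' protocols describe release of the epithelium with EDTA, dissociation with dispase and DNase, pooling by condition, and cell sorting. The sort kept EPCAM-positive, CD45-negative cells and loaded CD44-positive and CD44-negative cells at 1:1, so the balance of proliferating and differentiated cells is set by the sort. Libraries were made with a split-pool kit (Parse Biosciences Evercode WT), in which cells are barcoded in plates over several rounds. The 8 deposited samples are 8 sublibraries that each hold cells of every condition. The groups compared here therefore come from the sample names in the deposited cell table, which names 32 loaded samples: colon and cecum, each with Ctrl, Abx_4D, Abx_14D and GF, numbered 1 to 4. What 4D and 14D stand for is not stated, and the group names are used as deposited.

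The authors deposited 1 matrix of transcript counts (unique molecules per cell and gene, not normalised), a table of barcodes and a table of genes. Per the submitters' processing notes, the mouse build mm39 and Seurat were used, without versions, and the gene table names GRCm39. The aligner, the counting tool and the annotation release are not given in the sources used here. The matrix held 24609 barcodes, 33696 genes and 259517245 transcripts, and for every barcode the row sum equalled the total in the deposited cell table. Barcodes reached down to 30 transcripts.

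A barcode was kept as a cell with at least 500 transcripts. This left 15916 cells, which held 99.7% of all transcripts. The 8693 barcodes below it (35.3%) had a median of 58 transcripts. The plan had set the cells as deposited and assumed pooled samples with no replicates. Tests across the numbered samples depart from it, and no label names separate animals. The colon control samples kept 50 of 2299 barcodes and the colon Abx_4D samples 1026 of 7469. The kept cells had a median of 13472 transcripts, 4232.5 genes and 0.308% mitochondrial transcripts. In the median, 4 cecal samples had over 0.5% mitochondrial transcripts (Abx_4D 2, Abx_14D 3 and 4, GF 4). Scrublet called 25 of 6773 cecal cells (0.369%) and 20 of 9143 colon cells (0.219%), too few for a caller that works, so doublets were left in. The 26 gene symbols that occur more than once in the gene table were kept as separate features.

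Cells were clustered per tissue with scanpy 1.11.5 and igraph 0.11.9 under Python 3.11.15. Counts were normalised to 10000 per cell and log-transformed, 2000 variable genes and 30 principal components were used with 15 neighbours, and Leiden clusters were taken at resolution 1. A cluster was named from fixed cell type markers with a score of at least 0.4, at least 3 markers at 20 CPM, and no more markers of another class than of its own among its top 10 genes. The score was set after the data were seen. Of 21 cecal clusters, 5 were absorptive-like (colonocyte markers), 7 stem-like or proliferating-like, and 1 each goblet-like, enteroendocrine-like, tuft-like and immune-like. The other 5 stayed unnamed.

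Raw counts were summed per sample and class where a sample had at least 20 cells of the class. Sums were compared with edgeR 4.0.16 (quasi-likelihood test, library-size scaling, default low-count filter, R 4.3.3), with Benjamini-Hochberg adjustment and a threshold of 0.05. The 4 cecal groups shared 1 fit per class, the colon groups shared another, and colon and cecum samples of Abx_14D and GF were fitted together. Gene lists were compared with camera (limma 3.58.1) at a preset correlation of 0.01 and again with an estimated correlation, over members with at least 10 CPM in either group. Cell shares were compared with two-sided exact permutation tests. Levels are means of CPM over samples with their SD, and changes are log2 fold changes with their standard error. Where a group held 1 to 3 counts of a gene, the ratio of summed CPM is given with a 95% counting interval. With 0 counts, a bound is given against a floor of 3 counts over the group. Intervals and bounds cover counting error only. The labels do not say that the numbered samples are separate animals, so p-values measure only the spread between these samples, which may be technical.

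The tests, the markers and 24 gene lists were chosen before the data were examined. The lists are stem cell, cell cycle, proximal colon and cecum, distal colon, region transcription factors, nicotinic acid and NAD, fatty acid oxidation, short-chain fatty acid use, oxidative phosphorylation, cholesterol synthesis, antimicrobial, MHC class II, interferon, mucin and glycosylation, ion and water transport, xenobiotic response, bile acid, circadian clock, barrier and junction, regeneration, dissociation stress, ER stress, immune cells and stroma. The last 2 had fewer than 3 members at 10 CPM in the compared classes and could not be tested. Named genes of absorptive cells come from the 12 genes that rose most and the 12 that fell most among called genes with at least 50 CPM, the 8 each way with the largest smaller change of Abx and GF, and up to 4 members of each list described. In the other classes they come from 6 each way. Predicted genes, Rik genes, mitochondrial genes and ribosomal protein genes were left out. The text names part of these genes. The comparison of Abx_14D with Abx_4D was not part of the plan, and all of its called absorptive genes are named.

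The numbers in the sample names were tested as pairs, by the correlation over genes of the deviations from group means. Colon and cecum samples with the same number went together in absorptive cells (r from 0.193 to 0.308 in Abx_14D and from 0.121 to 0.349 in GF) and in stem and proliferating cells (from 0.212 to 0.404 and from 0.216 to 0.667), as did GF and Abx_14D colon samples in stem and proliferating cells (from 0.160 to 0.460). The source of this pairing is not stated.

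The test was run on simulated counts with 50 genes changed at each of 4 sizes. For cecal absorptive Abx_14D against Ctrl (9282 genes), it recovered 52% of 2-fold and 98% of 4-fold changes, with 8 false calls. For stem and proliferating cells it recovered 96% and 100%, with 16 false calls among 12000 genes. For goblet cells it recovered 24% and 96%, with 7 false calls among 9544 genes.

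Alternatives were TMM and median-of-ratios scaling, a total without mitochondrial, ribosomal protein and the top 20 genes, DESeq2 1.42.0, and limma on the mean of per-cell CPM (pseudocount 1). They also covered cells with at least 1000 transcripts and at most 10% mitochondrial, all cells pooled or weighted by class, Leiden resolution 0.5, classes from marker scores per cell, doublets left out, and other floors. Each sample and each sublibrary was left out in turn. Region genes were picked at 2-fold, with 1.5-fold and 4-fold as alternatives. Chosen after seeing the data were a block on the sample number, samples with at least 10 cells of a class, and the absorptive class with the unnamed clusters closest to it. The same holds for leaving out the 4 cecal samples named above, barcodes of 100000 or more transcripts, and absorptive cells with at least 0.5% goblet-marker transcripts.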

Results

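The data were transcript counts per cell, with 4 numbered samples per group and tissue. After the filter on depth, the cecal Ctrl samples held 1330 cells (191 to 453 per sample, 2573787 to 7489436 transcripts). The cecal Abx_4D samples held 1511 cells (191 to 557, 1821737 to 10009028 transcripts), the Abx_14D samples 2296 cells (356 to 971, 8068659 to 15414170 transcripts) and the GF samples 1636 cells (267 to 619, 6702465 to 14157157 transcripts). In the colon, the Abx_14D samples held 3852 cells (542 to 1886, 6613124 to 30127065 transcripts) and the GF samples 4215 cells (674 to 1425, 8544196 to 26697212 transcripts). Colon Ctrl held 50 cells and colon Abx_4D 1026, of which 857 came from 1 sample. The colon was thus compared between GF and Abx_14D only.

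**Figure D1:**
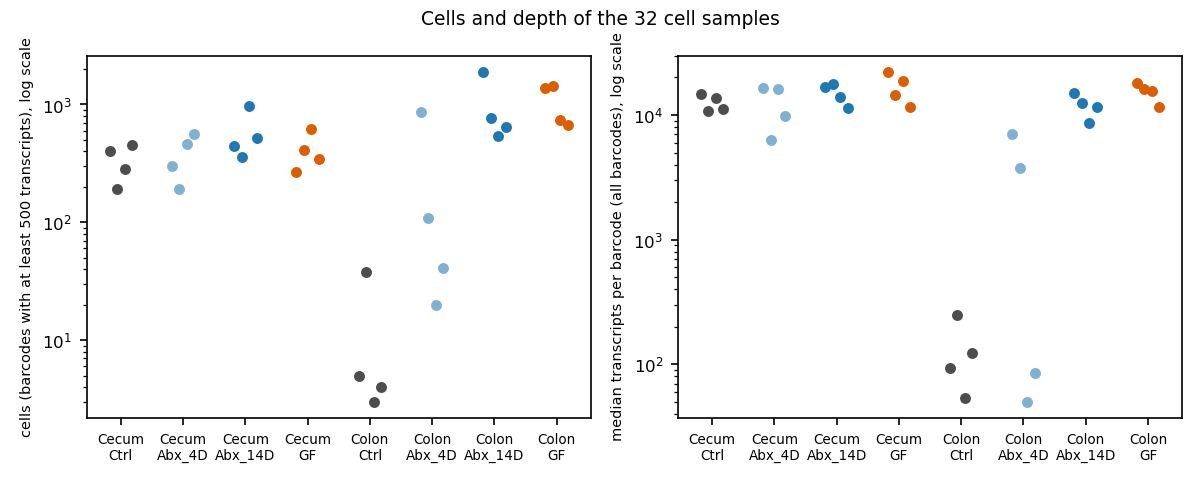
Cells per sample (barcodes with at least 500 transcripts) and median transcripts per barcode over all barcodes, both on log axes, 1 point per numbered sample in the 8 groups. The 4 colon Ctrl samples held 3 to 38 cells each.

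The series title concerns nicotinic acid from the microbiome, regional identity of the colon and susceptibility to injury. In the cecum, absorptive-like cells made up 19.6% ± 13.6 (SD, n = 4) of cells in Ctrl, 11.1% ± 7.75 in Abx_4D, 22.5% ± 11.3 in Abx_14D and 22.4% ± 10.3 in GF. Stem-like and proliferating-like cells made up 55.1% ± 13.2, 55.7% ± 7.27, 44.9% ± 10.5 and 43.2% ± 9.35 in the same order, and goblet-like cells 5.98% ± 2.91, 5.78% ± 1.61, 5.59% ± 0.629 and 8.10% ± 1.94. Tuft-like cells made up 1.31% ± 0.718, 0.358% ± 0.127, 0.513% ± 0.433 and 1.05% ± 0.406. None of the 35 share comparisons passed adjustment. The smallest two-sided exact permutation p was 0.0286, the smallest that 70 arrangements allow, and the smallest adjusted value was 0.25. Unnamed clusters held 15.4% ± 5.15, 24.8% ± 4.69, 24.4% ± 2.09 and 24.0% ± 1.75 of cells. Among them, the clusters closest to absorptive cells held 0.401% ± 0.524 in Ctrl, 3.29% ± 2.51 in Abx_4D, 7.34% ± 2.08 in Abx_14D and 7.71% ± 1.36 in GF. The cecal absorptive class also came from different clusters. Of the 306 Ctrl cells, 97.4% lay in 1 cluster that held 298 Ctrl cells of 300. All but 2 of the 200 Abx_4D, 593 Abx_14D and 383 GF cells lay in 4 others. Of these 4, 1 held 59.0% of the GF and 15.7% of the Abx_14D cells, and another 9.92% and 44.0%. In GF against Abx_14D, only the interferon list was followed within clusters. Plet1, B3galt5, Aqp8 and Ly6a are among the 10 leading genes of that control cluster. Slc10a2 and Rbp2, Ugt8a, and Slc22a4 are among those of clusters with 0, 1 and 5 Ctrl cells. Changes of these genes between groups, and of the bile acid list through Slc10a2, are not independent of the grouping of the cells.

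In cecal absorptive cells, Abx_14D (n = 4) against Ctrl (n = 3) asks what differs after antibiotics. Plet1, a surface protein, fell by 7.96 ± 0.43 (SE) on the log2 scale, from 416 ± 193 to 1.22 ± 0.876 CPM. The galactosyltransferase B3galt5 fell by 6.09 ± 0.39 and the oxidase Duox2 by 5.55 ± 0.46. Reg3b, an antibacterial lectin, fell by 8.35 ± 0.72 from 159 ± 113 CPM. Its relative Reg3g had 2 counts in Abx_14D, 361-fold lower (95% counting interval 99.2 to 2992). Cd74, the invariant chain of MHC class II, fell by 3.82 ± 0.39 from 366 ± 137 to 30.3 ± 19.7 CPM, and the class II chains H2-Ab1 and H2-Aa fell by 3.61 ± 0.38 and 4.03 ± 0.41. Aqp4, a water channel, fell by 4.30 ± 0.47, S100g, a calcium-binding protein, by 4.36 ± 0.45, Ly6a by 3.67 ± 0.34, the membrane mucin Muc4 by 3.54 ± 0.27 and the fucosyltransferase Fut2 by 2.44 ± 0.22. The gasdermins Gsdmc2, Gsdmc3 and Gsdmc4 fell by 3.16 ± 0.43, 3.17 ± 0.38 and 2.61 ± 0.37. They are close paralogs, and how shared reads were counted is not given. They are leading genes of an unnamed cluster outside the class (7 Ctrl, 60 Abx_4D, 180 Abx_14D and 121 GF cells). Their falls and those of the distal list are not independent of this grouping. Among genes that rose were Slc22a4, an organic cation transporter (3.87 ± 0.55, from 6.20 ± 4.19 to 65.3 ± 35.7 CPM), and the metallothioneins Mt1 (3.51 ± 0.45) and Mt2 (3.83 ± 0.55). Anxa1 (3.06 ± 0.37), Rbp2 (3.10 ± 0.40), Vldlr (2.89 ± 0.38) and Cobl (2.75 ± 0.26) also rose. Cyp4f14, Ugt8a and the peptidase Enpep rose by 2.49 ± 0.23, 3.06 ± 0.31 and 2.73 ± 0.51. Apob, the core protein of chylomicrons, rose by 2.44 ± 0.29, from 174 ± 45.2 to 966 ± 225 CPM, and Slc10a2, the bile acid importer of the ileum, by 2.42 ± 0.26. In edgeR, 353 genes rose and 347 fell of 9282 tested, 700 in all. The count was 407 without Ctrl 4, 422 without Ctrl 3, 466 without Abx_14D 3 and 285 without the samples that had over 0.5% mitochondrial transcripts.

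**Figure D2:**
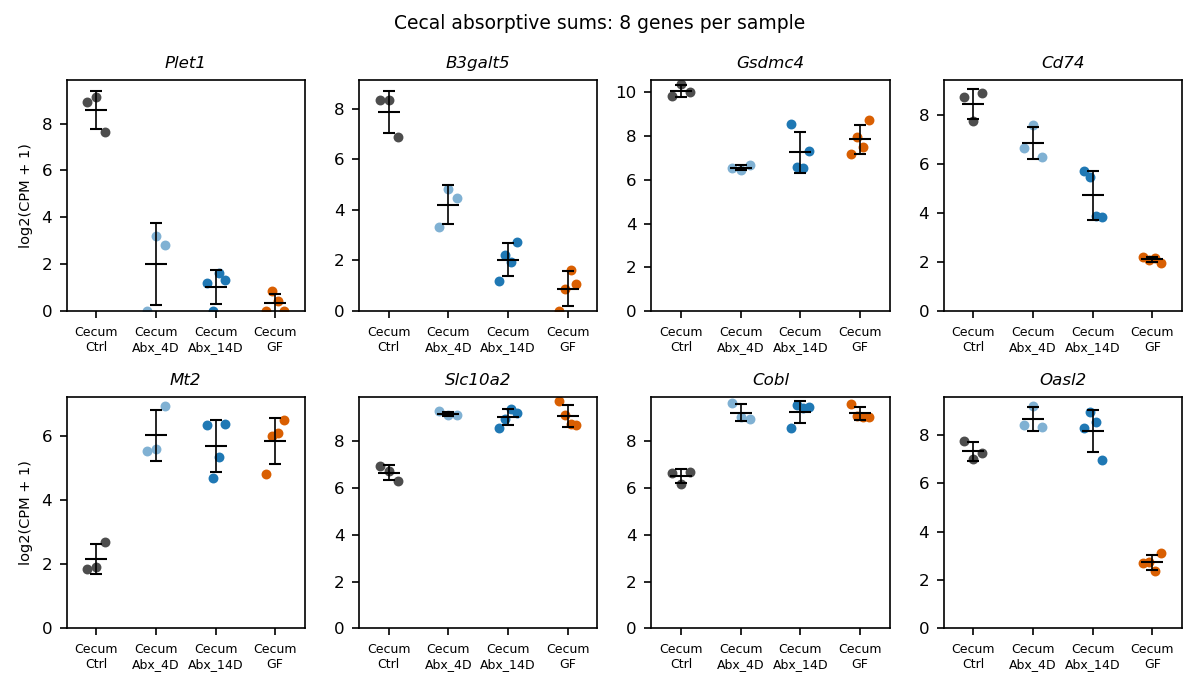
Level of 8 genes in cecal absorptive sums as log2(CPM + 1), 1 point per sample for Ctrl (n = 3), Abx_4D (n = 3), Abx_14D (n = 4) and GF (n = 4), with the mean and SD as lines. Plet1, B3galt5, Gsdmc4 and Cd74 lie below the Ctrl samples in each other group, and Mt2, Slc10a2 and Cobl lie above them.

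By the fixed lists, 9 of 14 measured antimicrobial genes fell after Abx_14D and none rose (9 and 0 when adjusted over the list alone). Their median log2 change was -1.43 (camera adjusted p = 5.1e-18, and 0.0020 with an estimated correlation). Of 7 MHC class II genes 6 fell and 0 rose (6 adjusted over the list alone), with a median of -3.80 (adjusted p = 1.1e-17, and 0.023 with an estimated correlation). Of 24 mucin and glycosylation genes 8 fell and 1 rose (10 and 2 adjusted over the list alone), among them Muc4 and Fut2 (median -0.25, adjusted p = 3.2e-06, and 0.034 with an estimated correlation). The distal colon list fell with 3 of 9 genes lower, the Gsdmc genes (4 lower and 1 higher adjusted over the list alone, median -0.62, adjusted p = 0.00015, and 0.033 with an estimated correlation). Of 6 bile acid genes 3 rose (3 adjusted over the list alone), among them Slc10a2 and the exporter subunit Slc51a (1.27 ± 0.26). Their median was 0.64 (adjusted p = 0.0013, but adjusted p = 0.21 with an estimated correlation). Of 14 circadian clock genes 5 rose and 1 fell (6 and 1 adjusted over the list alone, median 0.59, adjusted p = 0.0083, but adjusted p = 0.37 with an estimated correlation). Among them were the repressor Nr1d1 (1.75 ± 0.29) and the clock output factor Tef (2.21 ± 0.42). Tef missed the threshold at 1.63 without the samples over 0.5% mitochondrial. The xenobiotic response list had 6 of 28 genes higher and 0 lower (8 and 2 adjusted over the list alone, adjusted p = 0.013, but adjusted p = 0.42 with an estimated correlation, and 0.17 without Ctrl 2). Oxidative phosphorylation had 1 of 24 higher (3 adjusted over the list alone, adjusted p = 0.0041, but adjusted p = 0.73 with an estimated correlation).

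Of 17 genes of nicotinic acid and NAD metabolism, 2 fell after Abx_14D and 15 did not pass, with 2 adjusted over the list alone and no call for the list (adjusted p = 0.26). The 2 were Cd38, an enzyme that consumes NAD (fell by 2.36 ± 0.22, from 646 ± 185 to 126 ± 23.4 CPM), and Slc5a8, a transporter of short-chain monocarboxylates and nicotinate. Slc5a8 fell by 1.55 ± 0.22, from 260 ± 43.4 to 90.4 ± 11.6 CPM. The proximal colon and cecum list had 4 of 13 genes higher and 4 lower (4 and 4 adjusted over the list alone, adjusted p = 0.56). Apob, Slc10a2 and the fatty acid binding protein Fabp2 (1.56 ± 0.28) were among the first, and Aqp4 among the second. The interferon list had 3 of 34 genes higher and 5 lower (6 and 6 adjusted over the list alone, median 0.55, adjusted p = 0.32), and was called higher without Abx_14D 4 (adjusted p = 4.3e-06). The other lists were not called. Adjusted p was 0.34 for stem cell genes (0 of 10 higher or lower) and cell cycle genes (1 of 4 higher). It was 0.26 for region transcription factors (1 of 14 lower), 0.86 for fatty acid oxidation (2 of 29 each way) and 0.11 for short-chain fatty acid use (1 of 10 higher, 2 lower). It was 0.13 for cholesterol synthesis (1 of 21 higher), 0.43 for ion and water transport (6 of 29 higher, 3 lower) and 0.73 for barrier genes (2 of 27 each way). It was 0.49 for regeneration (3 of 11 each way), 0.26 for dissociation stress (2 of 18 lower) and 0.69 for ER stress (2 of 18 higher). Adjusted over the list alone, cholesterol synthesis had 6 higher, ion and water transport 8 higher and 5 lower and short-chain fatty acid use 2 higher and 3 lower. Dissociation stress had 1 higher and 4 lower, ER stress 3 higher, and the other 6 lists had the same counts. Dissociation stress was called lower without Abx_14D 3 (median -0.31, 0.0025), cholesterol synthesis higher without Abx_14D 2 (0.048) or sublibrary 4 (0.031), and stem cell genes lower without Abx_14D 2 (0.048) or sublibrary 3 (0.034). Short-chain fatty acid use was called lower without sublibrary 5 (0.050).

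In cecal absorptive cells of Abx_4D against Ctrl (n = 3 each), Plet1 fell by 6.03 ± 0.45, from 416 ± 193 to 4.74 ± 4.23 CPM. Aqp4 fell by 4.95 ± 0.62 and Reg3b by 4.21 ± 0.61. Gsdmc2 fell by 3.82 ± 0.51 from 1050 ± 408 to 70.1 ± 34.5 CPM, Gsdmc4 by 3.53 ± 0.44, B3galt5 by 3.53 ± 0.38, the cytokine Il18 by 3.19 ± 0.40 and Muc4 by 2.85 ± 0.30. Mt2 rose by 4.24 ± 0.57, Mt1 by 3.46 ± 0.47, Slc22a4 by 3.30 ± 0.59, Rbp2 by 2.93 ± 0.42, Cobl by 2.68 ± 0.27, Cyp4f14 by 2.17 ± 0.24 and Apob by 1.98 ± 0.29. Slc10a2 rose by 2.52 ± 0.28, from 101 ± 22.0 to 582 ± 38.7 CPM. The distal colon list fell, with 4 of 9 genes lower (5 adjusted over the list alone, median -0.72, adjusted p = 5.7e-07, and 0.012 with an estimated correlation). Antimicrobial genes had 5 of 14 lower (7 adjusted over the list alone, adjusted p = 3.2e-05, but adjusted p = 0.10 with an estimated correlation). Mucin and glycosylation genes had 5 of 24 lower and 1 higher (9 and 1 adjusted over the list alone, adjusted p = 0.00037, but adjusted p = 0.15 with an estimated correlation). Bile acid genes had 3 of 6 higher (3 adjusted over the list alone, adjusted p = 5.4e-05, but adjusted p = 0.14 with an estimated correlation). Interferon genes had 4 of 35 higher and 1 lower (9 and 1 adjusted over the list alone, median 0.83, adjusted p = 2.1e-06, but adjusted p = 0.48 with an estimated correlation). MHC class II genes had 2 of 7 lower (4 adjusted over the list alone, median -1.15, adjusted p = 0.00078, but adjusted p = 0.35 with an estimated correlation, and 0.059 without sublibrary 3). Oxidative phosphorylation (2 of 24 higher, 2 adjusted over the list alone, adjusted p = 0.0017) had adjusted p = 0.53 with an estimated correlation. Its median of 0.27 was -0.09 without Abx_4D 4, where the call was lost (0.43). Dissociation stress (1 of 18 lower, 1 adjusted over the list alone, adjusted p = 0.0012) had adjusted p = 0.48 with an estimated correlation. The proximal list (3 of 13 each way, 3 and 4 adjusted over the list alone, adjusted p = 0.71) and the NAD list (2 of 17 lower, 1 higher and 2 lower adjusted over the list alone, adjusted p = 0.47) were not called. In edgeR 170 genes rose and 263 fell of 9282, 433 in all. The count was 224 without Abx_4D 3, 226 without Ctrl 3, 252 without Ctrl 4 and 256 without sublibrary 3.

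In absorptive cells, 5 genes were lower in Abx_14D (n = 4) than in Abx_4D (n = 3). Duox2 fell by 4.14 ± 0.49, H2-Aa by 2.88 ± 0.45, B3galt5 by 2.56 ± 0.45, H2-Ab1 by 2.34 ± 0.40 and Cd74 by 2.24 ± 0.39. Apart from Duox2, these missed the threshold without Abx_4D 3 (-2.56, -2.27, -1.84 and -1.70) and without Abx_14D 3 (-2.85, -2.33, -1.99 and -1.91), and the count was 1 without Abx_14D 3, 2 without sublibrary 5 or 6 and 3 without Abx_4D 3. It was 8 without Abx_14D 1, Abx_4D 4 or sublibrary 7 and 9 without Abx_14D 2. DESeq2 called 10 genes and limma 0. No gene rose in edgeR, and 510 genes had an unadjusted p under 0.05. The antimicrobial list was lower in Abx_14D, with 1 of 12 genes called (7 adjusted over the list alone, adjusted p = 5.8e-17, and 0.0012 with an estimated correlation). MHC class II was lower too, with 3 of 4 called (4 adjusted over the list alone, adjusted p = 3.6e-24, and 0.0019 with an estimated correlation). Interferon genes had 0 of 35 called (4 lower adjusted over the list alone, adjusted p = 1.2e-10, but adjusted p = 0.40 with an estimated correlation), a call lost without Abx_14D 4 (0.12) or Abx_4D 3 (0.095). Of the genes called against Ctrl, 142 rose and 195 fell in both antibiotic groups (6.47 and 9.83 if independent), and the shared Ctrl samples raise such overlaps.

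In cecal absorptive cells of GF (n = 4) against Ctrl (n = 3), MHC class II and interferon genes fell together. Cd74 fell by 6.81 ± 0.49, from 366 ± 137 to 3.33 ± 0.323 CPM, and H2-Aa by 6.40 ± 0.55. H2-Ab1 was 242-fold lower (82.4 to 1179) and H2-Eb1 108-fold lower (36.3 to 526). The interferon-induced genes Zbp1, a sensor of nucleic acid, Oasl2 and Ifit1 fell by 5.56 ± 0.53, 4.83 ± 0.41 and 4.71 ± 0.54. Plet1 had 2 counts in GF, 1331-fold lower (368 to 1.1e+04), Reg3b was 600-fold lower (166 to 4961) and Reg3g 543-fold lower (96.9 to 21510). B3galt5 fell by 7.49 ± 0.46, Duox2 by 6.72 ± 0.52, Aqp4 by 6.08 ± 0.57, Ly6a by 5.89 ± 0.43 and Muc4 by 4.42 ± 0.29. Gsdmc4 fell by 2.10 ± 0.37, the water channel Aqp8 by 2.32 ± 0.41 and Gsdmc2 by 2.61 ± 0.42. Gsdmc2 was not called, at -0.95, when the unnamed clusters closest to absorptive cells were added, nor, at -0.46, when all cells were pooled. Slc22a4 rose by 4.20 ± 0.55, Susd4 by 4.17 ± 0.38, Mt2 by 4.02 ± 0.55, Ugt8a by 3.83 ± 0.31, Bmper by 3.73 ± 0.51, Enpep by 3.61 ± 0.51 and Mt1 by 3.42 ± 0.45. Apob rose by 2.82 ± 0.29, Cobl by 2.65 ± 0.26, Slc10a2 by 2.47 ± 0.27 and Slc51a by 1.82 ± 0.26. In edgeR 445 genes rose and 518 fell of 9282, 963 in all. The count was 528 without Ctrl 4 and 594 without Ctrl 3.

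All 32 measured interferon genes fell in GF (32 adjusted over the list alone), with a median log2 change of -3.59 (adjusted p = 7.4e-60, and 0.0093 with an estimated correlation). Of 7 MHC class II genes 6 fell (6 adjusted over the list alone, median -6.36, adjusted p = 1.3e-23, and 0.0081 with an estimated correlation). Antimicrobial genes had 9 of 16 lower and 2 higher (9 and 3 adjusted over the list alone, median -0.99, adjusted p = 6.2e-11, and 0.0081 with an estimated correlation). The distal colon list had 4 of 9 lower (5 adjusted over the list alone, median -1.12, adjusted p = 0.00030, and 0.022 with an estimated correlation). Regeneration genes had 5 of 10 lower, among them Ly6a, and 2 higher (7 and 2 adjusted over the list alone, median -1.29, adjusted p = 0.00031, but adjusted p = 0.054 with an estimated correlation). Dissociation stress genes had 7 of 18 lower (12 adjusted over the list alone, median -0.97, adjusted p = 1.4e-07, but adjusted p = 0.15 with an estimated correlation). Circadian clock genes had 8 of 15 higher and 4 lower (8 and 4 adjusted over the list alone, median 1.01, adjusted p = 0.0094, but adjusted p = 0.26 with an estimated correlation). Without GF 1 the list was not called (adjusted p = 0.091). Tef rose by 3.21 ± 0.42, Dbp, a clock output factor, was 41.2-fold higher (7.13 to 1652), and Nfil3, which represses the same sites, fell by 3.33 ± 0.52. Xenobiotic response (6 of 29 higher, 2 lower, 12 and 3 adjusted over the list alone, adjusted p = 0.017) had adjusted p = 0.27 with an estimated correlation, and the call was lost without Ctrl 2 (0.14) or GF 1 (0.053). Bile acid genes (2 of 6 higher, 2 adjusted over the list alone, adjusted p = 0.0018) had adjusted p = 0.17 with an estimated correlation.

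Of 17 NAD genes, 4 fell and 1 rose in GF (4 and 1 adjusted over the list alone). Cd38 fell by 2.14 ± 0.22 (from 646 ± 185 to 145 ± 30.6 CPM) and Slc5a8 by 1.29 ± 0.22. Parp14 and Parp9, ADP-ribosyltransferases that interferon induces, fell by 1.91 ± 0.28 and 1.45 ± 0.26. The list was called lower (adjusted p = 0.041, but adjusted p = 0.23 with an estimated correlation) although its median was 0.15. The call was lost without Ctrl 2 (0.060), GF 2 (0.059), GF 3 (0.066), GF 4 (0.060) or sublibrary 6 (0.13). Mucin and glycosylation genes had 6 of 27 higher and 8 lower (7 and 9 adjusted over the list alone, median -0.18, adjusted p = 0.0056, but adjusted p = 0.23 with an estimated correlation, and 0.079 without GF 1). The goblet genes Fcgbp (5.21 ± 0.65, 14.4 ± 5.07 to 476 ± 413 CPM), Clca1 (4.58 ± 0.76), Zg16 (4.23 ± 0.70) and Tff3 (4.13 ± 0.65) rose, and Fer1l6 was 119-fold higher (40.3 to 577). Of the 383 GF cells of this class, 6 cells held 90.6% of its goblet-marker transcripts. Without such cells, Clca1, Zg16 and Tff3 missed the threshold at 0.79, 0.14 and 0.79, Fcgbp passed it at 1.69, and Fer1l6 had too few counts to test. Without the 19 richest cells Fcgbp averaged 23.2 and Fer1l6 1.64 CPM, against 476 and 57.1. The proximal list had 4 of 14 higher and 1 lower (4 and 1 adjusted over the list alone, adjusted p = 0.15). Also not called were stem cell genes and cell cycle genes (0 of 9 and 0 of 4 higher or lower, adjusted p = 0.62 each), region transcription factors (1 of 15 higher, 0.79) and fatty acid oxidation (4 of 29 higher, 3 lower, 0.72). Neither were short-chain fatty acid use (2 of 10 lower, 0.059) and oxidative phosphorylation (3 of 24 higher, 1 lower, 0.72). The same holds for cholesterol synthesis (0 of 21, 0.74), ion and water transport (3 of 29 higher, 4 lower, 0.79), barrier genes (3 of 27 lower, 0.85) and ER stress (0 of 18, 0.14). Adjusted over the list alone, their counts were the same. ER stress was called lower without Ctrl 2 (0.021), and short-chain fatty acid use without Ctrl 2 (0.046), GF 4 (0.033) or sublibrary 1, 4 or 8 (0.034, 0.045 and 0.049).

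**Figure D3:**
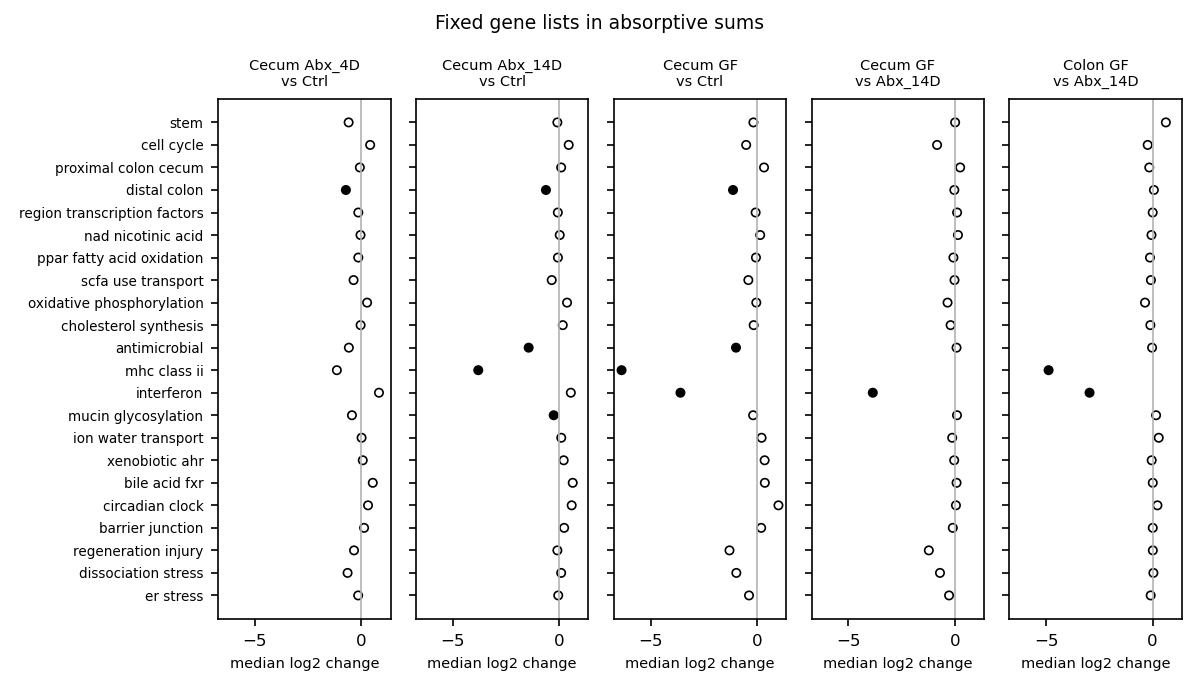
Median log2 change of each fixed gene list (y axis) in absorptive sums in 5 comparisons, on 1 shared x axis in log2 units; filled points mark an adjusted camera p under 0.05 with an estimated correlation. The interferon list lies at -3.59 in GF against Ctrl and at -3.85 and -2.97 in GF against Abx_14D of the cecum and colon.

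In absorptive cells 220 genes rose and 237 fell in both Abx_14D and GF against Ctrl. Independent calls would share 16.9 and 19.4, and 4 genes went opposite ways. Over 3976 genes with at least 50 CPM, the log2 changes correlated with r = 0.755 (Spearman's rho 0.724), and genes are not independent replicates. Both changes use the same Ctrl samples, and simulated counts with no group differences gave a mean r of 0.599 and a covariance of 0.0401, against 0.341 in the data. When each group was compared with its own part of the Ctrl samples, Ctrl 1 with its 11 cells included, r averaged 0.605 (0.50 to 0.701 over 6 splits). In stem and proliferating cells 81 genes rose and 185 fell in both (2.15 and 8.57 if independent), with r = 0.757 (rho 0.563) over 4820 genes against 0.513 in simulation, and 0.538 (0.351 to 0.717) with split controls.

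In cecal absorptive cells, interferon genes were lower in GF than in Abx_14D (n = 4 each). Oas2, Oasl2 and Isg15 fell by 5.86 ± 0.68, 5.77 ± 0.40 and 5.74 ± 0.56 in GF, Oasl2 from 321 ± 152 to 5.75 ± 1.42 CPM and Isg15 from 71.0 ± 32.7 to 1.65 ± 1.37 CPM. Ifit1 fell by 5.67 ± 0.51, Rsad2 by 5.36 ± 0.54 and Ddx60 by 3.87 ± 0.32. Of 34 interferon genes 31 fell and none rose (32 adjusted over the list alone, median -3.85, adjusted p = 8.2e-131, and 0.0017 with an estimated correlation). Parp14 and Parp9 fell by 1.87 ± 0.26 and 1.43 ± 0.24, as did Nampt, the enzyme that salvages nicotinamide, by 0.85 ± 0.21 (132 ± 20.1 to 74.7 ± 18.1 CPM). Without Abx_14D 2, Abx_14D 3, GF 2, GF 3 or GF 4, Nampt missed the threshold at -0.78, -0.79, -0.74, -0.81 and -0.88. They are the 3 of 17 NAD genes that fell (3 adjusted over the list alone, adjusted p = 0.36 for the list). Bmp3 rose by 2.44 ± 0.28 and Aoc1 by 1.75 ± 0.20. Clca1 (5.0 ± 0.66), Fcgbp (4.92 ± 0.54), Fer1l6 (4.89 ± 0.63) and Muc2 (3.22 ± 0.43) rose. Without goblet-rich cells, Clca1 and Muc2 missed the threshold at 1.23 and 0.87, Fcgbp passed it at 1.41, and Fer1l6 had too few counts to test. Dissociation stress genes had 6 of 18 lower (11 adjusted over the list alone, adjusted p = 1.8e-08, but adjusted p = 0.23 with an estimated correlation). Regeneration genes had 3 of 8 lower (6 adjusted over the list alone, median -1.22, adjusted p = 3.5e-06, but adjusted p = 0.19 with an estimated correlation), and cholesterol synthesis genes 2 of 21 (4 adjusted over the list alone, adjusted p = 0.0037, but adjusted p = 0.66 with an estimated correlation). Oxidative phosphorylation was called lower (0 of 24 genes, 1 adjusted over the list alone, adjusted p = 0.0019, but adjusted p = 0.66 with an estimated correlation, and 0.051 without Abx_14D 4). So were cell cycle genes (0 of 4, 2 adjusted over the list alone, adjusted p = 0.022, but adjusted p = 0.30 with an estimated correlation, and 0.29 without sublibrary 7). ER stress genes were called lower with 1 of 19 higher (1 higher and 2 lower adjusted over the list alone, adjusted p = 0.029, but adjusted p = 0.66 with an estimated correlation). That call was lost without Abx_14D 3 (0.097), Abx_14D 4 (0.055), GF 1 (0.12) or sublibrary 1, 4 or 7 (0.054, 0.059 and 0.052). The proximal list (1 of 13 higher, 1 adjusted over the list alone, adjusted p = 0.21) and the distal list (1 of 9 lower, 1 adjusted over the list alone, 0.96) were not called. The circadian clock list was not called either (1 of 14 lower, 2 each way adjusted over the list alone, adjusted p = 0.95). Neither were mucin and glycosylation genes (5 of 26 higher, 1 lower, 5 and 2 adjusted over the list alone, 0.30) and antimicrobial genes (2 of 12 higher, 4 adjusted over the list alone, 0.22), which were called higher without GF 1 (0.021 and 0.010). In edgeR 89 genes rose and 199 fell, 288 in all, and the count was 148 without Abx_14D 3, 176 without GF 3, 187 without GF 2 and 106 without the samples over 0.5% mitochondrial.

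In colon absorptive cells (n = 4 each), GF against Abx_14D also had lower interferon and MHC class II genes. Cd74 fell by 5.50 ± 0.47, from 176 ± 75.9 to 3.41 ± 2.84 CPM, and Ifi44 by 6.13 ± 0.74. Oas3 fell by 5.04 ± 0.72, Oasl2 by 4.13 ± 0.45 and Ddx60 by 3.95 ± 0.50, and Oas2 was 170-fold lower (46.7 to 1410). Of 30 interferon genes 24 fell (29 adjusted over the list alone, median -2.97, adjusted p = 3.1e-116, and 0.0095 with an estimated correlation). All 3 measured MHC class II genes fell (3 adjusted over the list alone, median -4.89, adjusted p = 2.3e-33, and 0.0033 with an estimated correlation). Of 19 NAD genes 2 fell (3 adjusted over the list alone, adjusted p = 0.0034, but adjusted p = 0.078 with an estimated correlation), among them Parp14 by 2.00 ± 0.28, which missed the threshold without GF 3 (-1.96). Stem cell genes were called higher with 0 of 13 passing (0 adjusted over the list alone, median 0.62, adjusted p = 3.6e-05, but adjusted p = 0.54 with an estimated correlation). Oxidative phosphorylation was called lower with 0 of 24 (0 adjusted over the list alone, adjusted p = 2.5e-07, but adjusted p = 0.54 with an estimated correlation). The proximal (0 of 14) and distal (0 of 11) lists had no gene called, 0 adjusted over the list alone, and adjusted p = 0.43 (0.045 without sublibrary 2) and 0.83. The genes that rose in edgeR were Rora, a nuclear receptor (4.22 ± 0.74), and Slc11a2, a metal ion transporter (1.69 ± 0.30). Rora missed the threshold without Abx_14D 2 (3.99), Abx_14D 3 (4.22), Abx_14D 4 (4.02), GF 2 (4.12) or GF 3 (3.69). Slc11a2 missed it without Abx_14D 2, 3 or 4 (1.77, 1.79 and 1.51), GF 3 or 4 (1.44 and 1.64) or sublibrary 4, 6, 7 or 8 (1.61, 1.56, 1.66 and 1.17). In all 56 genes were called, 54 of them lower, of 8774 tested. The count was 114 without Abx_14D 1, 25 without Abx_14D 2, 30, 29, 21 and 26 without GF 1 to GF 4, 33 without sublibrary 6 and 35 without sublibrary 7. Of the genes that fell, 51 of 53 tested in the cecum fell there too, and samples with the same number go together across the regions.

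In stem and proliferating cells of the cecum (n = 4 per group), Abx_4D against Ctrl had lower Reg3g (fell by 3.33 ± 0.37), Duox2 (by 2.73 ± 0.40), Cd177 (by 2.54 ± 0.39), the nitric oxide synthase Nos2 (by 2.50 ± 0.39) and Gsdmc4 (by 2.31 ± 0.27). Mt2 (2.77 ± 0.40) and Tfrc, the transferrin receptor (1.33 ± 0.21), rose. In Abx_14D, Reg3b fell by 6.56 ± 1.00, Cd177 by 5.51 ± 0.47, Nos2 by 4.97 ± 0.46, Duox2 by 4.80 ± 0.45, Reg3g by 4.20 ± 0.37 and H2-Ab1 by 3.17 ± 0.28. In the same group Mt2 (3.27 ± 0.40), Mt1 (2.33 ± 0.38), Adgrb3 (2.13 ± 0.24) and Pcdh17 (1.62 ± 0.23) rose. In GF, Cd74 fell by 6.64 ± 0.33, from 430 ± 52.1 to 4.25 ± 1.69 CPM, H2-Ab1 by 7.14 ± 0.42 and Iigp1, an interferon-induced GTPase, by 6.69 ± 0.56. Reg3b fell by 7.83 ± 1.16 and Reg3g by 5.68 ± 0.44, and Nos2 was 499-fold lower (138 to 4127). Mt2 (3.58 ± 0.40), Mt1 (2.44 ± 0.39), Adgrb3 (2.43 ± 0.24) and Malrd1 (1.78 ± 0.29) rose in GF. The antimicrobial list fell in all 3 comparisons, with 6 of 14, 9 of 14 and 8 of 15 genes lower (8, 10 and 9 adjusted over the list alone, with 1 higher in GF, adjusted p = 0.00036, 2.8e-05 and 0.00093 with an estimated correlation). MHC class II had 0 of 7 lower in Abx_4D (4 adjusted over the list alone, adjusted p = 1.4e-07, but adjusted p = 0.065 with an estimated correlation). It had 6 of 7 lower in Abx_14D and 7 of 7 in GF (7 each adjusted over the list alone, adjusted p = 2.8e-05 and 1.3e-05 with an estimated correlation). Interferon genes fell in Abx_14D (9 of 17, 12 adjusted over the list alone, adjusted p = 0.018 with an estimated correlation) and GF (15 of 16, 16 adjusted over the list alone, 0.00043). The distal list had 2 of 5 genes lower in both antibiotic groups (3 adjusted over the list alone, adjusted p = 0.0033 and 0.021 with an estimated correlation). In edgeR 75, 362 and 651 genes of 12000 were called in Abx_4D (16 higher), Abx_14D (99 higher) and GF (260 higher). The first count was 45 without Abx_4D 3 and 47 without Abx_4D 4, and the second 220 without Abx_14D 3, 240 without Abx_14D 2 and 156 without the samples over 0.5% mitochondrial.

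Between the groups without an intact microbiome, 11 stem and proliferating genes differed from Abx_4D to Abx_14D, 10 of them lower (6 without Abx_14D 3, 7 without Abx_4D 1 or Abx_4D 3). MHC class II had 5 of 6 lower (5 adjusted over the list alone, adjusted p = 2.5e-05 with an estimated correlation) and interferon 2 of 16 (11 adjusted over the list alone, adjusted p = 0.010 with an estimated correlation). In GF against Abx_14D of the cecum, Cd74 fell by 3.71 ± 0.32, while Rora (2.34 ± 0.37, from 13.4 ± 6.17 to 67.9 ± 14.6 CPM), Gsdmc4 (1.54 ± 0.25) and Pld5 (1.35 ± 0.21) rose. Interferon genes had 3 of 9 lower (6 adjusted over the list alone, adjusted p = 1.2e-08, but adjusted p = 0.11 with an estimated correlation). Cell cycle genes had 0 of 26 called (10 lower adjusted over the list alone, adjusted p = 1.4e-10, but adjusted p = 0.17 with an estimated correlation). In all 14 genes rose and 25 fell, 39 together. The count was 23, 13 and 24 without Abx_14D 1, 3 and 4, 18, 18, 13 and 23 without GF 1 to GF 4, 21 without sublibrary 1 or 7, and 17 without the samples over 0.5% mitochondrial. In the colon, Rora rose by 2.38 ± 0.14 in GF, from 59.6 ± 13.9 to 309 ± 32.3 CPM. Cd74 fell by 3.94 ± 0.43, Lgals9 by 1.45 ± 0.15, Parp14 by 1.44 ± 0.13 and Ly6e by 1.26 ± 0.16. There 19 of 20 interferon genes and 5 of 6 MHC class II genes fell (19 and 6 adjusted over the list alone, adjusted p = 0.0048 and 0.013 with an estimated correlation). In all 23 genes rose and 121 fell, 144 together (396 without GF 4).

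Goblet cells had fewer cells per sample (Ctrl and Abx_4D n = 2, Abx_14D and GF n = 4). In the cecum, Cd177 fell by 4.57 ± 0.54 in Abx_14D and by 4.21 ± 0.52 in GF, Duox2 by 3.89 ± 0.55 and 4.0 ± 0.55, and Cd74 by 3.59 ± 0.44 and 6.01 ± 0.55. Duox2 missed the threshold without Ctrl 2 (-3.20 in Abx_14D, -3.29 in GF), as did Cd74 in Abx_14D without sublibrary 3 (-2.96). MHC class II had 2 of 5 lower in Abx_14D and 5 of 5 in GF (5 each adjusted over the list alone, adjusted p = 0.0011 and 0.00061 with an estimated correlation). Interferon genes had 6 of 23 lower in GF (20 adjusted over the list alone, adjusted p = 0.017 with an estimated correlation). In edgeR 47 genes were called in Abx_14D (13 higher) and 69 in GF (24 higher). The first count was 4 without Ctrl 2, 31 without Ctrl 4, 25 without Abx_14D 1, 27 without Abx_14D 4 and 19 to 30 without a sublibrary from 1 to 7. The second was 21 without Ctrl 2 or Ctrl 4, 36 without GF 2 and 17, 15, 19, 41 and 28 without sublibrary 2, 3, 4, 5 or 8. Other settings moved these counts (below). Abx_4D against Ctrl and Abx_14D against Abx_4D had 0 calls in edgeR, with 695 and 406 genes at an unadjusted p under 0.05, while DESeq2 called 5 and 4 genes and limma 2 and 0. Without Ctrl 4 the former called 7, without sublibrary 2, 4 or 8 also 7 and without sublibrary 3 5. The latter called 2 without Abx_4D 3, 4 without Abx_4D 4 and 1 without sublibrary 2.  In GF against Abx_14D of the cecum 16 genes rose and 16 fell. Of 21 interferon genes 7 fell (18 adjusted over the list alone, adjusted p = 4.9e-23, but adjusted p = 0.084 with an estimated correlation), among them Oasl2 by 3.56 ± 0.56. Oasl2 missed the threshold without GF 1 (-3.54) and GF 3 (-3.31). The count of 32 was 1 and 6 without these, 6 and 12 without Abx_14D 1 and 3, 50 without Abx_14D 2, 8 without sublibrary 3 and 56 without sublibrary 6. In the colon Oas2 fell by 6.01 ± 0.45, Oasl2 by 3.91 ± 0.45, Cd74 by 3.60 ± 0.47 and B2m, the light chain of MHC class I, by 1.91 ± 0.16, and Rora rose by 1.68 ± 0.29. Rora missed the threshold without Abx_14D 2 (1.66), Abx_14D 3 (1.72) or sublibrary 6 (1.57). Interferon genes had 19 of 25 lower (24 adjusted over the list alone, adjusted p = 0.0022 with an estimated correlation), and 11 genes rose and 61 fell, 72 together (47 without Abx_14D 3).

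Colon and cecum were compared within Abx_14D and within GF (n = 4 each). In absorptive cells, Tgm3, a transglutaminase, was higher in the colon by 8.64 ± 0.54 in Abx_14D and 9.21 ± 0.55 in GF, the chloride channel Ano1 by 6.69 ± 0.56 and 6.46 ± 0.55 and Aqp4 by 6.16 ± 0.53 and 7.06 ± 0.62. Gna14 was higher by 6.25 ± 0.48 and 5.48 ± 0.45, St3gal6 by 6.19 ± 0.46 and 5.68 ± 0.46 and Thbs4 by 5.79 ± 0.60 and 6.77 ± 0.65. Atp12a, a proton pump, was 810-fold (224 to 6697) and 407-fold (112 to 3369) higher, and B3galt5 was higher by 6.29 ± 0.60 in GF. Lower in the colon were Ly6m in Abx_14D (fell by 6.88 ± 0.85), Adamts18 (by 4.47 ± 0.59 and 4.45 ± 0.50), Clca4a (by 4.03 ± 0.46 and 2.94 ± 0.43) and Saa3 (by 3.82 ± 0.57 and 3.93 ± 0.54). Mpp1 fell by 3.57 ± 0.36 and 3.90 ± 0.37, Tmigd1 by 3.18 ± 0.41 and 3.31 ± 0.42 and Abca12 by 2.98 ± 0.29 and 3.25 ± 0.30. The median log2 change of all genes was 0.31 in Abx_14D and 0.27 in GF. Stem cell genes had 12 of 13 higher and 1 lower in both (12 and 1 adjusted over the list alone, medians 2.56 and 2.98, adjusted p = 0.0014 and 1.0e-07, but adjusted p = 0.55 and adjusted p = 0.27 with an estimated correlation). Cell cycle genes had 8 of 11 and 8 of 12 higher (8 and 11 adjusted over the list alone, adjusted p = 0.19 and 0.0094, the latter with adjusted p = 0.53 with an estimated correlation). The first was called without Cecum Abx_14D 2 (0.049) or sublibrary 7 (0.014), and the second lost its call without sublibrary 2 (0.078). Xenobiotic response genes had 11 of 29 and 13 of 30 lower and 3 higher in each (12 and 15 lower adjusted over the list alone, adjusted p = 4.7e-06 and 2.3e-08, but adjusted p = 0.27 and adjusted p = 0.090 with an estimated correlation). Bile acid genes had 3 of 6 and 3 of 7 lower (4 each adjusted over the list alone, adjusted p = 0.0033 and 0.0019, but adjusted p = 0.36 and adjusted p = 0.29 with an estimated correlation). The proximal list had 6 of 14 and 7 of 14 lower and 5 and 4 higher (7 each lower adjusted over the list alone, medians -0.45 and -0.55, adjusted p = 0.019 and 0.00034, but adjusted p = 0.36 and adjusted p = 0.090 with an estimated correlation). In Abx_14D its call was lost with a block on the sample number (median -0.58, adjusted p = 0.050) and without Colon Abx_14D 1 (0.11), Colon Abx_14D 4 (0.053) or sublibrary 4 (0.097). Regeneration genes had 9 of 13 higher in GF (11 adjusted over the list alone, adjusted p = 0.00028, but adjusted p = 0.090 with an estimated correlation) and 6 of 13 in Abx_14D (7 adjusted over the list alone, 0.24). The distal list (4 of 11 each way, and 4 of 12 higher, adjusted p = 0.82 and 0.73) and ion and water transport (10 of 32 higher and 12 lower, 13 of 33 higher and 8 lower, 0.16 and 0.83) were not called. Neither were NAD genes (5 of 18 higher and 1 lower, 7 of 19 higher and 1 lower, 0.55 and 0.97). Adjusted over the list alone, ion and water transport had 11 higher and 13 lower in Abx_14D and 16 and 8 in GF, and the counts of the distal and NAD lists were the same.

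**Figure D4:**
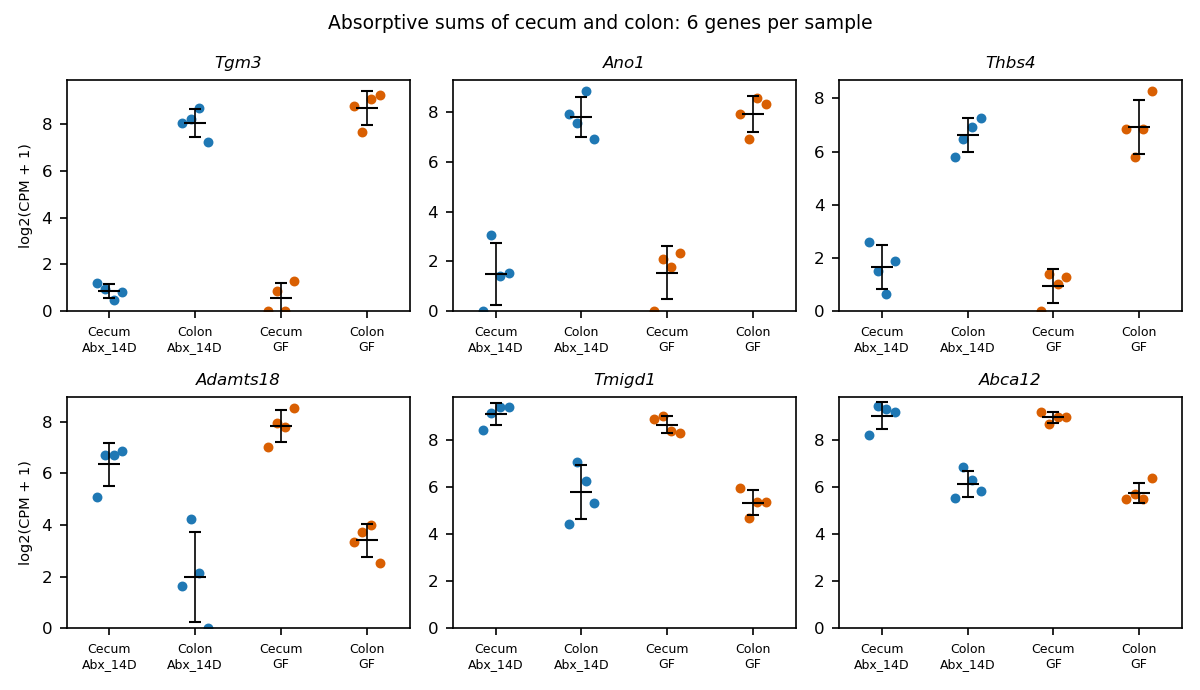
Level of 6 genes in absorptive sums of cecum and colon in Abx_14D and GF as log2(CPM + 1), 1 point per sample (n = 4 per group), with the mean and SD as lines. Tgm3, Ano1 and Thbs4 lie higher in each colon sample than in any cecum sample, and Adamts18, Tmigd1 and Abca12 lie lower.

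In edgeR 3405 absorptive genes differed between colon and cecum in Abx_14D (2645 higher, 760 lower, 9569 tested) and 2862 in GF (2263 and 599). The counts were 2169 without Colon Abx_14D 1 and 1906 without Colon GF 2, and the first was 1711 without the samples over 0.5% mitochondrial. Of these, 1780 genes were higher and 423 lower in both, where independent calls would share 626 and 47.6. The balance depends on the scaling, with 1647 higher and 1462 lower by TMM in Abx_14D and 1480 and 1281 in GF. In stem and proliferating cells, Nxpe2 was higher in the colon by 7.42 ± 0.34 in Abx_14D and 7.16 ± 0.35 in GF and Thbs4 by 6.09 ± 0.33 and 6.86 ± 0.38. Ptprt was higher by 5.58 ± 0.28 and 6.07 ± 0.31 and B3galt5 by 5.51 ± 0.32 and 6.62 ± 0.36. Lower were Gal3st2c (by 5.86 ± 0.22 and 5.89 ± 0.21) and Slc37a2 (by 5.64 ± 0.24 and 5.39 ± 0.23). St3gal5 fell by 5.35 ± 0.17 and 5.25 ± 0.17 and the carbonic anhydrase Car4 by 4.42 ± 0.32 and 4.35 ± 0.29. Of 26 cell cycle genes 23 and 12 were lower (24 and 18 adjusted over the list alone, adjusted p = 3.5e-09 and 2.1e-05, but adjusted p = 0.23 and adjusted p = 0.49 with an estimated correlation). Proliferating-like clusters held 207 and 106 of 2242 colon Abx_14D cells, against 264, 126 and 107 of 964 in the cecum. In GF they held 238 and 144 of 2294, against 106, 75 and 79 of 703. Cell cycle values were not told apart from this mix. Mucin genes had 12 of 28 higher in each (12 and 13 adjusted over the list alone) and xenobiotic genes 15 of 28 lower in each (16 and 18 adjusted over the list alone). Both lists had adjusted p = 0.14 in Abx_14D and 0.046 in GF with an estimated correlation. In all 4627 genes differed in Abx_14D and 2435 in GF. In goblet cells, Mptx1 was higher in the colon by 8.56 ± 0.60 and Sval1 by 6.43 ± 0.49 in Abx_14D, B3gnt7 284-fold (78.4 to 2345), Hoxb13, a distal homeobox factor, 154-fold (27.4 to 6078) and Gcnt1 at least 54.4-fold. In GF, B3galt5 was 1108-fold (199 to 43770), Plet1 573-fold (103 to 22660) and Ccn3 at least 109-fold higher. St3gal5 fell by 4.65 ± 0.35 and 4.96 ± 0.36 and, in GF, the hormone gene Sct by 3.80 ± 0.64. Mucin genes had 13 of 33 higher in each (16 and 15 adjusted over the list alone) and oxidative phosphorylation 22 and 9 of 24 lower (22 and 16 adjusted over the list alone), with adjusted p of 0.13 to 0.23 with an estimated correlation. In all 1611 and 875 genes differed. The difference between the colon and cecum effects of GF against Abx_14D was tested with an interaction. In edgeR it called 0 absorptive genes (418 at an unadjusted p under 0.05), 0 goblet genes (676) and 1 stem and proliferating gene (845). DESeq2 called 9, 21 and 19 and limma 0 in each. With 1 sample or sublibrary left out, edgeR called at most 4 absorptive, 9 goblet and 5 stem and proliferating genes. These were without Colon Abx_14D 1, sublibrary 6 and Cecum GF 3. The 1 gene was Tceal8 (-2.01 ± 0.31, adjusted p = 0.030). It missed the threshold without 11 of 16 samples and 5 of 8 sublibraries (-2.08 to -1.78).

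Genes that differed between colon and cecum were then followed in the cecum. In absorptive cells, 498 genes higher in the colon by GF samples had a median log2 change of -0.27 in Abx_14D against Ctrl, with 22 higher and 69 lower (camera p = 5.9e-08, but p = 0.14 with an estimated correlation). The 166 genes higher in the cecum had a median of 0.38, with 52 higher and 6 lower (p = 1.1e-14, but p = 0.057 with an estimated correlation). By genes picked in Abx_14D, GF against Ctrl had medians of -0.09 for 507 colon genes (p = 0.00059, but p = 0.37 with an estimated correlation) and 0.18 for 230 cecum genes (p = 0.00042, but p = 0.44 with an estimated correlation). With 1 sample or sublibrary left out they were -0.29 to -0.02 and 0.13 to 0.25. With TMM scaling, the colon genes had medians of -0.40 in Abx_14D (p = 0.018 with an estimated correlation) and -0.32 in GF (p = 0.093 with an estimated correlation). These absorptive values also depend on how the class is drawn. With the unnamed clusters closest to absorptive cells added, the 4 medians in the same order were 0.14, 0.14, 0.45 and -0.05, and with classes from marker scores 0.06, 0.16, 0.29 and -0.05. In stem and proliferating cells after Abx_14D, 108 colon genes had a median of -0.30 (15 lower and 3 higher, p = 0.020 with an estimated correlation). The 107 cecum genes had 0.22 (16 higher and 4 lower, p = 4.4e-06, but p = 0.086 with an estimated correlation). In GF the medians of 156 colon and 200 cecum genes were -0.04 and -0.08. Neither was called by camera, with values of 0.11 and 0.26. Both were called without Ctrl 4 (-0.15 and 0.04, with 0.0015 and 0.0048) and without GF 1 (-0.11 and 0.03, with 0.0029 and 0.0063), as were the colon genes without Abx_14D 3 (-0.06, with 0.040). With an estimated correlation these values were 0.28 to 0.55. At 4-fold instead of 2-fold both were called, with medians of -0.37 (p = 7.4e-05, but p = 0.066 with an estimated correlation) and 0.23 (p = 2.0e-06, and p = 0.019 with an estimated correlation).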

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

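Counting Ctrl cells in clusters without GF cells and searching the labels for a day, cage or facility were tests chosen after the results were seen, and the other tests below were chosen before.

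Of 64 groups of 4 samples compared for cell numbers, depth, mitochondrial transcripts and class shares, 2 had 1 sample far from the other 3, where chance flags about 1 in 20 groups. Goblet-like cells made up 8.17% of Cecum Abx_4D 3 (4.70 to 5.24 in the others), and Colon GF 4 had a median of 0.285% mitochondrial transcripts (0.226 to 0.235). Of 298 groups of 4 samples compared for named genes, 29 had a sample far from the others. In CPM of absorptive sums, Cecum Abx_14D 1 was low for Adamts18 (33.2), Bmp3 (7.67), Cobl (379) and Slc22a4 (14.1), and Abx_14D 4 for Isg15 (22.8). Cecum Abx_14D 2 had 1.83 of Atp12a and 0 of Fer1l6, Cecum Abx_14D 3 42.4 of Muc4, Cecum GF 1 780 of Cobl and 23.7 of Dbp, and Cecum GF 4 1.09 of H2-Eb1 and 0.363 of Reg3g. Colon GF 1 had 553 of Aqp4, Colon GF 2 0.637 of Oas2 and Colon Abx_14D 2 51.5 of Mpp1. In stem and proliferating sums, Cecum GF 4 had 0 of B3galt5 and 644 of Pld5, GF 1 6.77 of Cd74, and Ctrl 2 5.64 of Mt2. Cecum Abx_14D 4 had 10.1 of H2-Ab1, 304 of Mt2 and 0.273 of Thbs4, Abx_14D 1 3.93 of Reg3b and Abx_4D 2 815 of Tfrc. In goblet sums the values were 1.30 of B3galt5 (Cecum GF 1), 16 of Cd74 (Colon GF 1), 1.29 of Hoxb13 (Cecum Abx_14D 1), 636 of Mptx1 (Colon Abx_14D 1) and 1.0 of Plet1 (Cecum GF 3).

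The effect of GF against Abx_14D differed between colon and cecum for Tceal8 in stem and proliferating cells (-2.01 ± 0.31, adjusted p = 0.030, and from 3.3e-05 to 0.40 over its alternatives). In colon barcodes outside the comparisons, the proximal colon and cecum list summed to 3186 to 8586 CPM in the 4 Ctrl samples, above the 2392 to 2851 of the 8 colon samples used. Oxidative phosphorylation summed to 6736 to 1.42e+04 CPM in the 4 colon Abx_4D samples, against 4775 to 5974. Other lists lay below the samples used, in Ctrl stem (1069 to 3558, against 4130 to 6432), clock (484.6 to 941.4, against 1007 to 1292) and region factor genes (2250 to 4879, against 5032 to 5396), and the last also in Abx_4D (3665 to 4924). Ctrl barcodes had medians of 54 to 250 transcripts, and no explanation of these signals was tested.

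Interferon genes were lower in GF than in Abx_14D in cecal absorptive cells (median -3.85). The tables argue against RNA of immune cells, which would bring 0.00248% of the interferon CPM at the share their markers allow (Ptprc at 0.204 CPM, against 1577 in 41 immune-like cells, which the sort on CD45 was set to remove). They argue against another mix of clusters, since the 4 absorptive clusters taken alone had medians of -4.78 to -1.83, and against sublibraries, with -4.61 to -2.10 in the 8 taken alone. Another collection day, cage or rearing facility cannot be told apart from GF, because 0 samples carry such a label. The state of the microbiome, which the design names, also stays open.

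Goblet genes were higher in GF than in Ctrl cecal absorptive cells. Free RNA would raise them in other classes too, but the excess of 12 goblet markers in stem and proliferating sums (127 CPM) was 10.7% of that in absorptive sums (1187 CPM). A candidate explanation is goblet cells or doublets within the class, since the 5% of GF cells richest in goblet markers, 19 of 383, held 94.5% of their transcripts. No biological explanation was tested.

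Clock genes moved in GF against Ctrl cecal absorptive cells, with a clock score higher by 3.42 ± 0.37 (1.31 ± 0.36 in Abx_4D and 2.38 ± 0.49 in Abx_14D). The tables argue against another time of day as the whole cause if the clock runs alike in both classes, since the score moved by 0.48 ± 0.18 in stem and proliferating cells, 14% of the absorptive change, but they leave this open for Abx_4D (0.44 ± 0.31) and Abx_14D (0.57 ± 0.17). The score moved by 2.83 ± 0.27 with the unnamed clusters closest to absorptive cells added and by 2.49 ± 0.19 with classes from marker scores, 72.9%. Another mix of absorptive cells cannot be told apart, because 95.2% and 80.1% of the Ctrl cells of these classes lay in a cluster with 0 GF cells. A hypothesis that stays open is that the state of the microbiome moves the clock of absorptive cells, and the hour of collection is not in the labels.

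Samples were also split in all other ways into groups of the same sizes and fitted again as 2 groups. For absorptive Abx_14D against Ctrl the real split called 753 genes and the highest other 457 (Abx_14D 1 placed with the 3 Ctrl samples). The real split also led for GF against Ctrl (1089 and 263) and GF against Abx_14D (243 and 39). A lead in 1 of 35 splits, the fewest possible, argues against chance for each comparison taken alone. It was not adjusted over the comparisons. It also covers only these numbered samples, and cannot speak to chance differences between animals or pools. For Abx_4D against Ctrl (464, highest other 0) the 10 splits are too few. Chance cannot be excluded for Abx_14D against Abx_4D, where 5 of 35 splits called as many as the real 3 (highest other 15). In colon GF against Abx_14D the count alone cannot exclude chance, as 2 of 35 splits called as many as the real 56. The highest other called 307, with Abx_14D 1 placed with GF 1, 2 and 3, and points to a structure of the samples that was not tested. But 51 of 53 lower genes fell in the cecum too (1.06 if independent), which argues against chance for these, sample pairing aside. In stem and proliferating cells the real split led in Abx_4D (52, highest other 10), Abx_14D (289 and 7) and GF (537 and 7) against Ctrl. It led in GF against Abx_14D (30 and 10), but not in Abx_14D against Abx_4D. There 2 of 35 splits called as many as the real 8 (highest other 11). In goblet cells the real split led for GF against Abx_14D in cecum (21 and 7) and colon (72 and 6). It also led there for colon against cecum (1324 and 6 in Abx_14D, 830 and 7 in GF). Where the numbers pair samples, the 8 splits that part as many pairs are too few, and those other than the real one called 0. The comparisons are colon against cecum in absorptive (2692 and 2682) and stem and proliferating cells (4491 and 2127), and colon GF against Abx_14D in the latter (144). Splits that keep a pair together called up to 8, or 351 in stem and proliferating GF (Cecum GF 1 with Colon GF 1, 2 and 3).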

How the results depend on the processing

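The alternatives chosen after the data were seen are named above. Of 224 gene values, 175 kept their direction and their side of the threshold under all alternatives run and none reversed. Of 129 list values, 74 kept both. TMM, median-of-ratios scaling and cells with at least 1000 transcripts moved no total of called genes by over 1.5 times. The 45 Scrublet doublets were too few to test a result by leaving them out. Not run were a 2-fold threshold for list counts, cells thinned to equal depth and parts of the control cells for picking region genes. Where no reason is given, the cause was not tested.

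Counts of called genes are given as main value to alternative, for comparisons named by their first group where the other is Ctrl. With DESeq2, stem and proliferating genes went from 75 to 191 (Abx_4D), 362 to 551 (Abx_14D), 39 to 100 (GF against Abx_14D), 11 to 19 (Abx_14D against Abx_4D), 144 to 265 (colon) and 1 to 19 (interaction). Goblet genes went from 0 to 5, 47 to 76, 32 to 82, 0 to 4, 72 to 124 and 0 to 21. The order is the same. With limma on per-cell means, absorptive counts were 253 (Abx_4D), 358 (Abx_14D), 191 (GF against Abx_14D), 0 (Abx_14D against Abx_4D) and 2199 (region in Abx_14D). Stem and proliferating counts were 231 (Abx_14D), 21 (GF against Abx_14D), 1597 (region in GF) and 0 (interaction), and goblet counts 2 (Abx_4D), 15 (Abx_14D), 45 (GF) and 21 (GF against Abx_14D). With no low-count filter, absorptive counts were 665 (Abx_4D), 493 (GF against Abx_14D), 90 (Abx_14D against Abx_4D), 133 (colon) and 118 (interaction). Stem and proliferating counts were 257 (Abx_4D), 658 (Abx_14D), 999 (GF), 252 (GF against Abx_14D), 89 (Abx_14D against Abx_4D), 389 (colon) and 25 (interaction), and goblet counts in the same order 86, 229, 307, 272, 33, 332 and 70. With all cells pooled, the absorptive counts became 66 (Abx_4D), 286 (Abx_14D), 86 (GF against Abx_14D), 8 (Abx_14D against Abx_4D) and 152 (colon), and weighted by class 209, 421 and 127 in the first 3. At Leiden resolution 0.5 absorptive counts were 1588 (GF), 619 (GF against Abx_14D), 121 (colon), 5935 and 4492 (region) and 35 (interaction), the stem and proliferating interaction 0, and goblet counts 17 (GF against Abx_14D) and 1 (Abx_14D against Abx_4D). With classes from marker scores, absorptive counts were 97 (colon), 5702 and 5009 (region) and 3 (interaction), the stem and proliferating interaction 0, and goblet counts 1 (Abx_4D), 457 (GF), 2 (Abx_14D against Abx_4D) and 1637 (region in GF). The tuft share difference of Abx_4D from Ctrl went from -0.956 to -1.14. A total without the top genes gave 1 goblet gene in Abx_14D against Abx_4D.

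The replicate block gave 9 absorptive (Abx_14D against Abx_4D), 121 (Abx_4D) and 4 (interaction) stem and proliferating, and 4 (Abx_4D), 80 (Abx_14D), 127 (GF), 58 (GF against Abx_14D), 1 (Abx_14D against Abx_4D) and 2 (interaction) goblet genes, and changed no other count by over 1.5 times. Samples with at least 10 cells gave 1 absorptive (Abx_14D against Abx_4D) and 5 and 3 goblet genes (Abx_4D and Abx_14D against Abx_4D). The wider absorptive class gave 1899 (GF), 3 (Abx_14D against Abx_4D), 97 (colon), 5326 and 4501 (region) and 8 (interaction) genes. Without the samples over 0.5% mitochondrial, fewer samples gave 285 (Abx_14D), 106 (GF against Abx_14D), 0 (Abx_14D against Abx_4D) and 1711 (region in Abx_14D) absorptive genes, 156, 17, 5 and 2922 stem and proliferating genes in the same order with 0 for the interaction, and 20, 4 and 866 goblet genes (Abx_14D, GF against Abx_14D and region in Abx_14D). Without very deep barcodes there were 3 absorptive (Abx_14D against Abx_4D) and 20 and 1 goblet genes (GF against Abx_14D and interaction).

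The correlation of Abx_14D and GF changes was 0.742 in absorptive cells at a floor of 10 CPM. With split controls it was 0.605, and 0.538 in stem and proliferating cells. Absorptive region genes higher in colon went from -0.27 to 0.057 (marker scores) and 0.14 (wider class) in Abx_14D, and from -0.09 to 0.29, 0.45, 0.27 (Leiden 0.5), 0.0048 (1.5-fold) and -0.32 (TMM) in GF. Those higher in cecum went from 0.38 to 0.14 (wider class, call lost) and from 0.18 to -0.0468 (marker scores) and -0.0475 (wider class). Stem and proliferating region genes in GF were called by camera at -0.37 (colon, 4-fold), -0.051 (colon, block) and 0.23 (cecum, 4-fold), with values of 7.4e-05, 0.042 and 2.0e-06 (0.066, 0.53 and 0.019 with an estimated correlation).

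List medians reversed in absorptive cells as follows. The NAD list in GF went from 0.15 to -0.052 (limma), -0.067 (pooled), -0.040 (weighted), -0.90 (floor of 50 CPM) and -0.020 (without deep barcodes), in Abx_14D from 0.03 to -0.0152 (floor), in GF against Abx_14D from 0.15 to -0.0153 (floor) and in the colon from -0.06 to 0.0025 (wider class). With pooled cells, interferon went to -0.068 (Abx_4D) and -0.20 (Abx_14D), clock genes to -0.12 and dissociation stress to -0.15 (Abx_14D), and by weighting to -0.13, -0.022 and -0.31 (Abx_14D). Dissociation stress in Abx_14D was -0.30 at 10 cells and -0.80 without the mitochondrial samples, and barrier genes in GF -0.038 by marker scores. Between regions, pooling gave cell cycle medians of -1.0 and -0.30 and ion transport medians of -0.45 and -0.48. Ion transport in Abx_14D was -0.23 (Leiden 0.5), -0.28 (marker scores) and -0.029 (floor).

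With 1 sample or sublibrary left out (a lone goblet control being assumed to vary like other groups), tuft share differences ranged from -1.18 to -0.697 (Abx_4D) and 0.407 to 0.853 (colon), and the goblet share difference of GF from Abx_14D from 1.95 to 3.17. Absorptive counts ranged over 224 to 393 (Abx_4D), 407 to 851 (Abx_14D), 528 to 1015 (GF), 148 to 359 (GF against Abx_14D), 1 to 9 (Abx_14D against Abx_4D), 21 to 114 (colon), 2169 to 3566 and 1906 to 3140 (region) and 0 to 4 (interaction). Stem and proliferating counts ranged over 45 to 75 (Abx_4D), 220 to 352 (Abx_14D), 13 to 34 (GF against Abx_14D), 6 to 16 (Abx_14D against Abx_4D), 106 to 396 (colon) and 0 to 5 (interaction). Goblet counts ranged over 0 to 7 (Abx_4D), 4 to 45 (Abx_14D), 15 to 80 (GF), 1 to 56 (GF against Abx_14D), 0 to 4 (Abx_14D against Abx_4D), 47 to 82 (colon) and 0 to 9 (interaction). Correlations ranged over 0.703 to 0.781 and 0.654 to 0.801. Stem and proliferating region genes in GF ranged over -0.15 to 0.023 and -0.20 to 0.042. List medians that reversed ranged over -0.31 to 0.26 (dissociation stress in Abx_14D), -0.17 to 0.0095 (NAD in colon) and -0.091 to 0.50 (oxidative phosphorylation in Abx_4D).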

Other observations

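The values below come from the gene lists chosen before the data were examined and from the cell table, and naming these lists here was decided after their values were seen.

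In stem and proliferating cells, ER stress genes were lower in GF than in Ctrl, with 9 of 19 called (12 lower and 1 higher adjusted over the list alone, median -0.58, adjusted p = 1.4e-07, but adjusted p = 0.24 with an estimated correlation). In Abx_14D against Ctrl 0 of 19 passed in edgeR (11 lower and 1 higher adjusted over the list alone, median -0.46, adjusted p = 4.5e-06, but adjusted p = 0.25 with an estimated correlation). In absorptive cells of Abx_14D, 4 of 5 MHC class II genes were higher in colon than in cecum (5 adjusted over the list alone, median 2.56, adjusted p = 0.0093, but adjusted p = 0.36 with an estimated correlation). That call was lost without sublibrary 5 (0.073), at Leiden resolution 0.5 (0.22) and with classes from marker scores (0.11).

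The colon control barcodes, most of them below the minimum of 500 transcripts, held 1269 to 3944 CPM of the carbonic anhydrase Car1 in the 4 samples, against 207 to 367 CPM in the 8 colon samples used. Of the 383 GF cecal absorptive cells, 13 barcodes with at least 100000 transcripts, the deepest with 532444, held 38.2% of the transcripts. Without such barcodes in any group, 298 absorptive genes were called in Abx_4D against Ctrl, 728 in Abx_14D and 902 in GF.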
